A study of Mus musculus with 10 samples.

How the data were processed

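RNA was measured by translating ribosome affinity purification followed by sequencing (TRAP-seq), in which ribosomes carrying an EGFP-tagged ribosomal protein L10a are captured from one cell class and the RNA bound to them is sequenced. Per the labels, the mice carried the tag under the Drd1 promoter (line CP73), so that the tagged cells are those expressing the dopamine D1 receptor, chiefly the direct-pathway medium spiny neurons of the striatum. The whole striatum was homogenised and tagged polysomes were captured with antibodies against EGFP, per the labels' protocols. There were 9 pull-down libraries in 3 groups of 3 (saline self-administration, cocaine self-administration and a yoked control) and 1 input library of total RNA. The labels do not say what the yoked mice received, nor that the libraries of a group came from separate animals, so p-values here measure only the spread between these samples, which may be technical.

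The deposited values are whole-number read counts per gene symbol. Reads were aligned with STAR 2.0.0e and counted with HTSeq on mm10, per the submitters' processing notes. The annotation, the strand setting, the counting mode and the HTSeq version are not given in the sources used here. Without a stated strand setting, reads of a gene and of a gene overlapping it on the other strand cannot be told apart, and near-identical copies such as ribosomal protein genes and their pseudogenes may share reads. Each deposited file held counts for 32531 gene rows and 6 rows naming no gene, namely a row called unknown and 5 HTSeq summary lines, which were left out of library sizes and tests. Reads in no annotated feature were 12.3% to 16.1% of uniquely aligned reads in the pull-downs and 27.6% in the input, and reads matching more than 1 gene were 2.54% to 3.03% and 6.63%.

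The pull-downs held 12.5 to 45.2 times 1e+06 counts in genes and the input 40.5 times 1e+06. Each saline library was shallower than each cocaine and yoked library. A count of 3, taken as the detection floor, corresponds to 0.0663 to 0.239 CPM (counts per 1e+06 gene counts) in the pull-downs, and it covers counting error only. The ribosomal RNA gene Rn45s took 10.5% to 20.5% of the gene counts of a pull-down. Counts of replicate pairs differed by far more than sampling noise (chi-square per degree of freedom 15.3 to 169), so no library was counted as a duplicate. The sequencing lane given in the labels differed between the groups (lane 3 for saline, 1 for cocaine, 2 for yoked, 5 for the input), so lane and group cannot be told apart.

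Differences between groups were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test with robust estimation, TMM normalisation, filterByExpr) on the counts of all 9 pull-downs, with the group as the only term. The 3 comparisons were cocaine against saline, cocaine against yoked and yoked against saline. A total of 14680 genes passed the filter, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The common biological coefficient of variation was 23.7%. Standard errors are the log2 fold change divided by the root of its F statistic. Gene lists were tested with camera of limma 3.58.1 at the preset inter-gene correlation of 0.01, adjusted over 78 tests (26 lists in 3 comparisons). Camera with an estimated correlation and fry were run beside it. Of 28 lists, the mitochondrially encoded genes matched no row and the blood markers had fewer than 3 tested genes. A list's score in a library is the mean log2 CPM of its members, compared between groups by a two-sided exact permutation test, whose smallest p for 3 libraries against 3 is 0.1.

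The lists were immediate early genes, dopamine and cAMP signalling, neuropeptides and their receptors, glutamate receptors and postsynaptic density, GABA signalling, ion channels, actin and spine genes, chromatin regulators, circadian clock, glucocorticoid-responsive genes, chaperones and ER stress, nuclear-encoded oxidative phosphorylation, cytosolic ribosomal proteins, mitochondrially encoded genes, presynaptic vesicle genes and sex-linked genes, and markers of D1, D2 and all medium spiny neurons, astrocytes, oligodendrocytes and their precursors, microglia, endothelial and mural cells, ependyma and choroid plexus, interneurons, cortical glutamatergic neurons and blood. Lists, tests, most alternatives and the rule for naming genes were fixed before the data were examined. The rule names the 10 largest and the 10 smallest fold changes among called genes with separated groups and a mean count of at least 50. It leaves out the sex-linked list and, by patterns in their symbols, predicted, unnamed and small RNA genes. The patterns did not cover clones with AK symbols, so such clones could be named. Where fewer than 5 genes qualify, as in all 3 comparisons here, it names the 10 genes with the smallest unadjusted p that meet the other conditions, given as not passing. It adds up to 4 called members of each list, of which there were none, and always Drd1, Tac1, Pdyn, Fos, Fosb, Arc, Drd2 and Penk. For the input comparison it names up to 4 of the most highly expressed members of each cell type list. Some of the genes so named are not reported here.

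Enrichment over the input was computed as log2 of TMM-scaled CPM plus 0.5 in each pull-down minus that of the input. With 1 input library it has no test, and each list's median was placed among 10000 random lists matched on mean expression. Coordinates are those of the RefSeq annotation of GRCm38.p6, the assembly of mm10, which matched 24162 (74.3%) of the gene rows and 13945 (95.0%) of the genes tested. Only its genomic spans were used as gene lengths, and no GC check was made here.

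The gene test was tested on simulated counts with the real means, library sizes and dispersions and 200 changed genes per run, in 3 runs of 14680 genes for each comparison. The changed genes were drawn only from those with an expected mean count of at least 50, so the shares do not cover weaker genes. For cocaine against saline, 22.0% of the genes changed 1.5-fold were called, 56.7% of those changed 2-fold, 88.0% of those changed 3-fold and 96.0% of those changed 4-fold. For cocaine against yoked the shares were 19.3%, 66.7%, 92.0% and 97.3%, and for yoked against saline 14.0%, 63.3%, 88.0% and 98.0%, in the same order of folds. Of 420, 440 and 422 calls in these 3 comparisons, 26, 27 and 27 were unchanged genes. For the list test, a separate simulation per comparison shifted only the oxidative phosphorylation list, by 1.2-fold. The list was called in each of the 3 comparisons, with 0 of the other lists called beside it. Genes and libraries were drawn independently in these simulations, whereas the estimated correlation within this list was 0.477 in the real cocaine against saline data. The simulations therefore do not show how often lists of correlated genes are called without a change. The share of changed genes called may also differ in the real libraries.

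Alternatives were DESeq2 1.42.0, limma-voom, 2 other normalisations, no filter and a stricter one (1 CPM in at least 6 libraries), a fit of only the groups compared, the replicate number as a block, each library left out in turn, a background covariate (mean log2 CPM of astrocyte, oligodendrocyte, microglia and endothelial markers), library sizes without Rpl10a and the 10 most abundant genes, a test against a 1.2-fold change, a pseudocount of 2 CPM for the input comparison, and an unadjusted p under 0.01 for overlaps. Figures were drawn with matplotlib 3.10.9.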

Results

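Ribosome-bound RNA of Drd1-expressing cells was sequenced from the whole striatum of mice of a short-access study of intravenous cocaine self-administration. In self-administration an animal responds for its own infusions, and a yoked control is in general an animal whose delivery is set by another animal's responding. What the yoked mice received is not given in the labels. There were 3 pull-downs each from saline self-administration, cocaine self-administration and yoked mice, and 1 input library of total striatal RNA. Libraries are called by their group and number (saline 1, for example). Depth, in units of 1e+06 gene counts, was 21.4 ± 8.12 in the saline group, 32.8 ± 0.634 in the cocaine group and 42.5 ± 3.45 in the yoked group (SD, n = 3 each), and 40.5 in the input.

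The comparison of pull-downs with the input asked how far RNA of the tagged cells was enriched. The single input, the reference of every ratio below, also held growth hormone (Gh) RNA at 2360 CPM and prolactin (Prl) RNA at 174 CPM, whose source was not tested. Markers of D1 medium spiny neurons were higher in the pull-downs than in the input, with a median ratio of 2.30 over 10 genes, above 99.99% of expression-matched random lists. Tac1, the precursor of substance P (chromosome 6, 7555061 to 7562978), was at 355 ± 108 CPM in the pull-downs (SD, n = 9) against 71.7 in the input, a 4.75-fold enrichment. Drd1 itself (chromosome 13, 54051183 to 54055658) was at 695 ± 120 against 322 CPM, 2.13-fold. Eya1 and Sfxn1 were enriched 2.27-fold and 2.34-fold. Markers of D2 medium spiny neurons, the indirect-pathway cells, were at a median of 0.264 of the input (percentile 0), with Penk, the enkephalin precursor, at 0.241 and the adenosine receptor gene Adora2a at 0.118. Gucy1a3 and Six3 of the same list were near the input level, at 0.879 and 0.992. Markers shared by both neuron classes lay at a median ratio of 1.16 (percentile 31.53). Among them Ppp1r1b, which encodes DARPP-32, was at 1.98, Arpp21 at 1.39, Pde10a at 1.2 and Gnal at 1.14.

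Glial RNA was depleted. Median ratios to the input were 0.190 for astrocyte markers, 0.128 for oligodendrocyte markers, 0.157 for oligodendrocyte precursor markers and 0.208 for microglial markers, each at percentile 0 of expression-matched random lists but the precursors, at 0.04. The glutamate transporter gene Slc1a2 was at 0.105 of its input level and Mobp, a myelin gene, at 0.0679, whereas Mbp was at 0.240 and Glul at 0.316. Aldoc was at 0.349, Cnp at 0.350 and Slc1a3 at 0.190. Among precursor markers Olig1, Pdgfra, Gpr17 and Olig2 were at 0.115, 0.157, 0.132 and 0.106 of the input, and among microglial markers Csf1r, Ctss and Cx3cr1 were at 0.170, 0.290 and 0.115. Endothelial and mural markers had a median ratio of 0.413 (percentile 7.63), with Rgs5 at 0.139, Pdgfrb at 0.253, Flt1 at 0.277 and Vtn at 0.308. Interneuron markers had a median of 0.364 (percentile 0.26), with Sst at 0.193, Npy at 0.263, Nos1 at 0.449 and the choline transporter gene Slc5a7 at 0.164. Ependymal and choroid plexus markers had a median of 0.369 (percentile 0.79), with Enpp2 at 0.292, Foxj1 at 0.212, Dynlrb2 at 0.956 and Ttr at 0.392. The Ttr ratio was 0.242 without saline 3, and Ttr was above the input in 2 of the 9 pull-downs. The 4 blood genes detected, Hbb-bs, Alas2, Hba-a2 and Hbb-b2, had a median of 0.316 (percentile 7.98) and few counts. With a pseudocount of 2 CPM in place of 0.5 the log2 ratio moved from -1.28 to -0.58 for endothelial, from -2.27 to -1.42 for microglial, from -1.44 to -0.67 for ependymal and from -1.66 to -0.74 for blood markers. Markers of cortical glutamatergic neurons had a median ratio of 1.57 to the input (percentile 99.98), with Slc17a7 at 1.70, Tbr1 at 2.31 and Neurod6 at 2.27. Of their 10 genes, 6 were above the input, 0 were above it in all 9 pull-downs and 2 were below it in all 9. The list median differed between libraries, from -0.49 to 1.46 on the log2 scale.

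**Figure D1:**
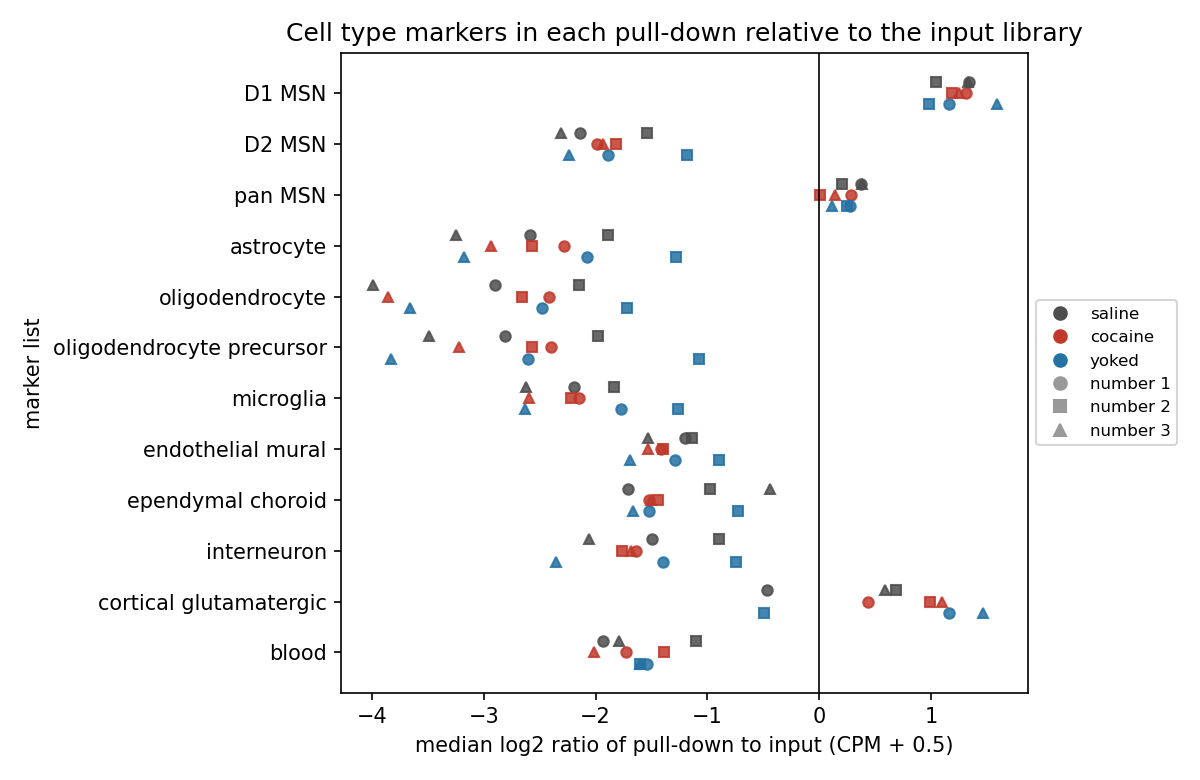
Median log2 ratio of each cell type marker list in each pull-down relative to the single input library, on the scale of CPM plus 0.5; colours give the group, circles, squares and triangles the libraries numbered 1, 2 and 3, and D1 markers lie between 0.98 and 1.59 in the 9 pull-downs and oligodendrocyte markers between -4.00 and -1.72.

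Of 12189 genes, 21 were at least 4-fold enriched and 177 at least 4-fold depleted in each of the 9 pull-downs. The single genes named here were chosen after their values were seen. Nuclear-encoded oxidative phosphorylation genes were enriched, with a list median of 3.19 times the input and 74 of 75 members above it in each pull-down. Ndufb2 of complex I was enriched 6.15-fold, Atp5e of the ATP synthase 5.86-fold and Cox5b of complex IV 5.87-fold. Among the depleted were noncoding RNAs retained in the nucleus. Malat1 was at 182 ± 81.6 CPM against 37000 in the input, 216-fold lower, and Meg3 was 53.3-fold, Miat 23.7-fold and Neat1 16.6-fold lower. Among other lists, dopamine and cAMP signalling genes had a median ratio of 1.42, ribosomal protein genes 1.54, chaperones 1.47, immediate early genes 1.32, actin and spine genes 1.32, presynaptic genes 1.25, circadian genes 1.24, glucocorticoid-responsive genes 1.01, GABA signalling 0.941, postsynaptic genes 0.903, neuropeptides 0.902, chromatin regulators 0.870, ion channels 0.839 and sex-linked genes 0.547.

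The level of glial RNA left in the pull-downs differed between libraries of the same group. The glial score, the mean log2 CPM of astrocyte, oligodendrocyte and microglial markers averaged over the 3 lists, was 2.54 ± 0.67 in saline, 2.58 ± 0.45 in cocaine and 2.90 ± 0.92 in yoked libraries (SD, n = 3). It was 1.95 ± 0.11 in the libraries numbered 3, 2.81 ± 0.20 in those numbered 1 and 3.26 ± 0.49 in those numbered 2, each set holding 1 library of each group.

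Cocaine was compared with saline self-administration to find ribosome-bound RNAs that differ with the drug. D1 neuron transcripts were at like levels in both groups. Drd1 was at 671 ± 58.1 CPM in cocaine and 675 ± 89.7 in saline libraries (SD, n = 3 each), a log2 fold change of -0.0095 ± 0.18 (SE), and Tac1 was at 344 CPM in both. Pdyn, the dynorphin precursor, was at 127 ± 13.5 and 125 ± 36.3 CPM. The immediate early gene Fos (chromosome 12, 85473890 to 85477274) was at 6.27 ± 3.67 CPM after cocaine and 2.45 ± 1.39 after saline, a log2 fold change of 1.30 ± 0.66 that did not pass (edgeR unadjusted p = 0.0755) and was 0.81 without cocaine 3. Arc was at 63.8 ± 11.5 and 46.4 ± 3.66 CPM and Fosb at 23.1 ± 4.71 and 24.6 ± 0.524. Drd2 and Penk, of the D2 marker list that was depleted in the pull-downs, had log2 fold changes of -0.46 ± 0.64 and 0.21 ± 0.23. Which cells this RNA came from was not tested.

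No gene was called between cocaine and saline by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (smallest adjusted p = 0.999). At an unadjusted p under 0.05 there were 417 of 14680 genes, where the nominal share of 0.05 is 734. Other splits of the same libraries gave 149 to 739. DESeq2 called 1 gene and limma-voom 0. That gene, the clone AK155692, which the reference table used here does not place, was also first by edgeR, at 176 ± 14.8 CPM in cocaine and 70.4 ± 9.87 in saline libraries. Its log2 fold change was 1.32 ± 0.25 (edgeR unadjusted p = 1.1e-04). DESeq2 gave it an adjusted p of 0.0024 by Benjamini-Hochberg. Over the other alternatives its adjusted p ran from 2.87e-04, by edgeR without yoked 3, to 1, without cocaine 2 or cocaine 3, and its log2 fold change from 1.21 to 1.40. In yoked libraries 1, 2 and 3 it stood at 143, 153 and 62.6 CPM of the library total. The other 9 genes named by the rule did not pass either. Higher values after cocaine were seen for Ciart, a repressor of the circadian clock (chromosome 3, 95878500 to 95882257), at 16.4 ± 3.56 against 9.52 ± 1.0 CPM, and for Cox8a, a complex IV subunit (chromosome 19, 7215158 to 7217616), at 673 ± 48.1 against 457 ± 14.7 CPM. Log2 fold changes were 0.76 for Rpain, 0.57 for Lin7b, 0.60 for Nt5c, 0.58 for the splicing factor Snrpd3 and 0.47 and 0.50 for the BLOC-1 subunits Dtnbp1 and Bloc1s1. Tshz2, a zinc finger gene, had lower ones, at 2.06 ± 0.127 against 5.48 ± 2.02 CPM. In each of these 10 genes the 3 cocaine libraries lay on one side of the 3 saline libraries, as the rule requires. Over genes with a mean count of at least 50, 1389 of 11601 (12%) were separated in this way, where chance gives 10%.

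Of the gene lists, 7 of 26 were called by camera. Nuclear-encoded oxidative phosphorylation genes rose in cocaine, with a median log2 fold change of 0.28 (1.22-fold) and higher values for 74 of 75 members (adjusted p = 3.4e-25, Benjamini-Hochberg, camera of limma). With an estimated correlation the adjusted p = 0.887. The list score was 7.03 ± 0.14 in cocaine and 6.76 ± 0.11 in saline libraries (SD, n = 3), fully separated (exact permutation p = 0.1, the smallest possible). Cocaine 1 was at 6.88 and saline 1 at 6.86, whereas cocaine 2 and cocaine 3 were at 7.14 and 7.08. The ribosomal RNA gene Rn45s took 11.4% of the gene counts in cocaine 1, 16.9% in cocaine 2 and 20.5% in cocaine 3, and 16.3 ± 4.57% in the cocaine, 12.5 ± 1.91% in the saline and 15 ± 0.29% in the yoked group (SD, n = 3). Of the 75 genes, 0 were called over all genes and 0 when adjusted over the list alone. Counts of cytosolic ribosomal protein genes leave out alignments that were not unique. These genes rose by a median of 0.25, with 74 of 80 higher (camera of limma, Benjamini-Hochberg adjusted p = 8.97e-11, and adjusted p = 0.887 with an estimated correlation). Their median was 0.14 without cocaine 2 (camera adjusted p = 0.0125, Benjamini-Hochberg) and 0.38 without cocaine 1, whose score of 3.55 lay below those of saline 1 and saline 2 (3.60 and 3.71). Glucocorticoid-responsive genes (0.19, 15 of 17 higher, camera adjusted p = 0.0403 by Benjamini-Hochberg) and cortical glutamatergic markers (0.49, 8 of 8 higher, 0.0443) were also called higher, each with an adjusted p = 0.887 with an estimated correlation. Ion channel genes fell by a median of 0.18, with 31 of 37 lower (camera adjusted p = 4.99e-04 by Benjamini-Hochberg, and adjusted p = 0.887 with an estimated correlation). Postsynaptic and glutamate receptor genes (-0.11, 30 of 37 lower, 0.00664) and chromatin regulators (-0.12, 28 of 41 lower, 0.0307) were lower. With an estimated correlation each of these 7 lists had a camera adjusted p of 0.887 (Benjamini-Hochberg), and fry called 0 lists. Of the lists called higher, oxidative phosphorylation, ribosomal, glucocorticoid and cortical genes had median ratios to the input of 3.19, 1.54, 1.01 and 1.57. Of those called lower, ion channels, postsynaptic genes and chromatin regulators had 0.839, 0.903 and 0.87. Some lists not called also lay above it, such as chaperones (1.47) and dopamine and cAMP signalling (1.42). Whether the shifts arose in the pull-down was not tested. Across genes, which are not independent replicates, the log2 fold change ran against genomic span (Spearman rho -0.299, 13288 genes). The tenth of genes with the shortest span had a median of 0.16 and the tenth with the longest -0.11. The deviation of a library from the mean of all 9 had a rho with span of -0.342 in cocaine 2 and -0.219 in cocaine 3 but 0.109 in cocaine 1. In saline 1, saline 2 and saline 3 this rho was 0.0142, 0.0464 and 0.195. Oxidative phosphorylation and ribosomal genes were called whichever library was left out, but 4 lists were called without saline 3 and 5 without cocaine 2. Ion channels were not (medians of -0.06 and -0.08, camera adjusted p = 0.369 and 0.549, Benjamini-Hochberg), nor were postsynaptic genes (medians of -0.03 in both, 0.388 and 0.287) and chromatin regulators (0.0969 and 0.209, with a median of -0.06 without cocaine 2), while the glucocorticoid list was lost without saline 3 (median 0.08, 0.133) or cocaine 1 (0.134) and the cortical list without saline 1 (median 0.07, 0.681), cocaine 1 (0.0737), cocaine 3 (0.197), yoked 1 (0.0545) or yoked 3 (0.0736). Without saline 3 the cortical median was 0.79, and without saline 2 the postsynaptic one was -0.16. Without the libraries numbered 3, an alternative chosen after the data were seen, the postsynaptic and cortical calls were lost (camera adjusted p = 0.0795 and 0.0606, Benjamini-Hochberg), and the medians of oxidative phosphorylation, ion channel and postsynaptic genes were 0.18, -0.11 and -0.07. With 12 lists called without saline 2, the count of lists rested on single libraries.

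**Figure D2:**
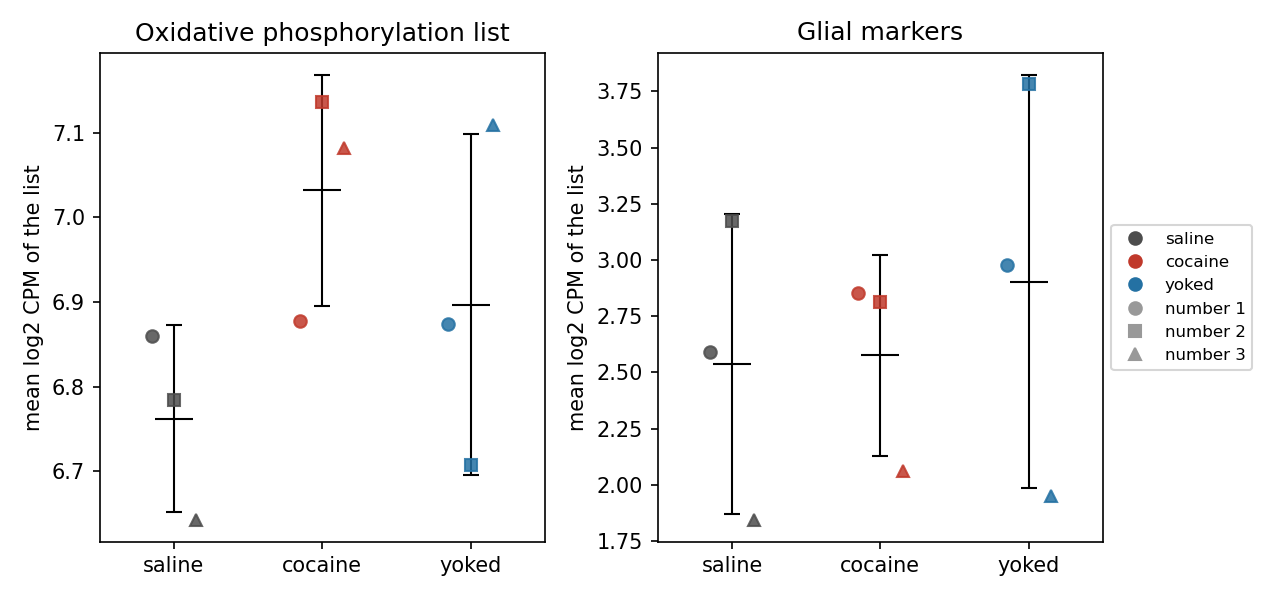
Mean log2 CPM of the nuclear-encoded oxidative phosphorylation list (left) and of the glial markers (right) in each of the 9 pull-downs by group; bars give the mean and SD of 3 libraries, and circles, squares and triangles the libraries numbered 1, 2 and 3. The oxidative phosphorylation scores average 7.03 in cocaine and 6.76 in saline libraries, and the 3 libraries numbered 3 have the lowest glial score of their group.

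The remaining lists were not called between cocaine and saline. Immediate early genes had a median log2 fold change of 0.10, circadian genes 0.11, and neuropeptides and receptors 0.02. Dopamine and cAMP signalling was at -0.02, GABA signalling at -0.09, presynaptic vesicle genes at -0.05, actin and spine genes at 0.0063, chaperones at -0.0091 and sex-linked genes at 0.09. Adjusted over the list alone, 1 circadian gene passed, Ciart (edgeR, Benjamini-Hochberg adjusted p = 0.0241), and 0 genes in any other list. Adjustment over 1 list does not allow for the number of lists and comparisons. Over all genes Ciart had an edgeR adjusted p of 0.999 (Benjamini-Hochberg). Of the cell type lists, D1 markers were at -0.0081, D2 markers at -0.0034, shared medium spiny neuron markers at -0.13, astrocyte at 0.09, oligodendrocyte at -0.09, precursor at -0.45, microglial at 0.0040, endothelial at -0.36, ependymal at -0.09 and interneuron markers at -0.19. Glial medians turned with single libraries. Without saline 2 they were 0.47 for astrocyte, 0.57 for oligodendrocyte and 0.42 for microglial markers, without saline 3 they were -0.31, -0.42 and -0.44, and without cocaine 3 they were 0.29, 0.23 and 0.21. The astrocyte median was also below 0 without cocaine 1 (-0.02) or cocaine 2 (-0.12). The mean had the other sign than the median for dopamine signalling, neuropeptides, chaperones and microglial markers, and camera the other direction than the median for chaperones.

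**Figure D3:**
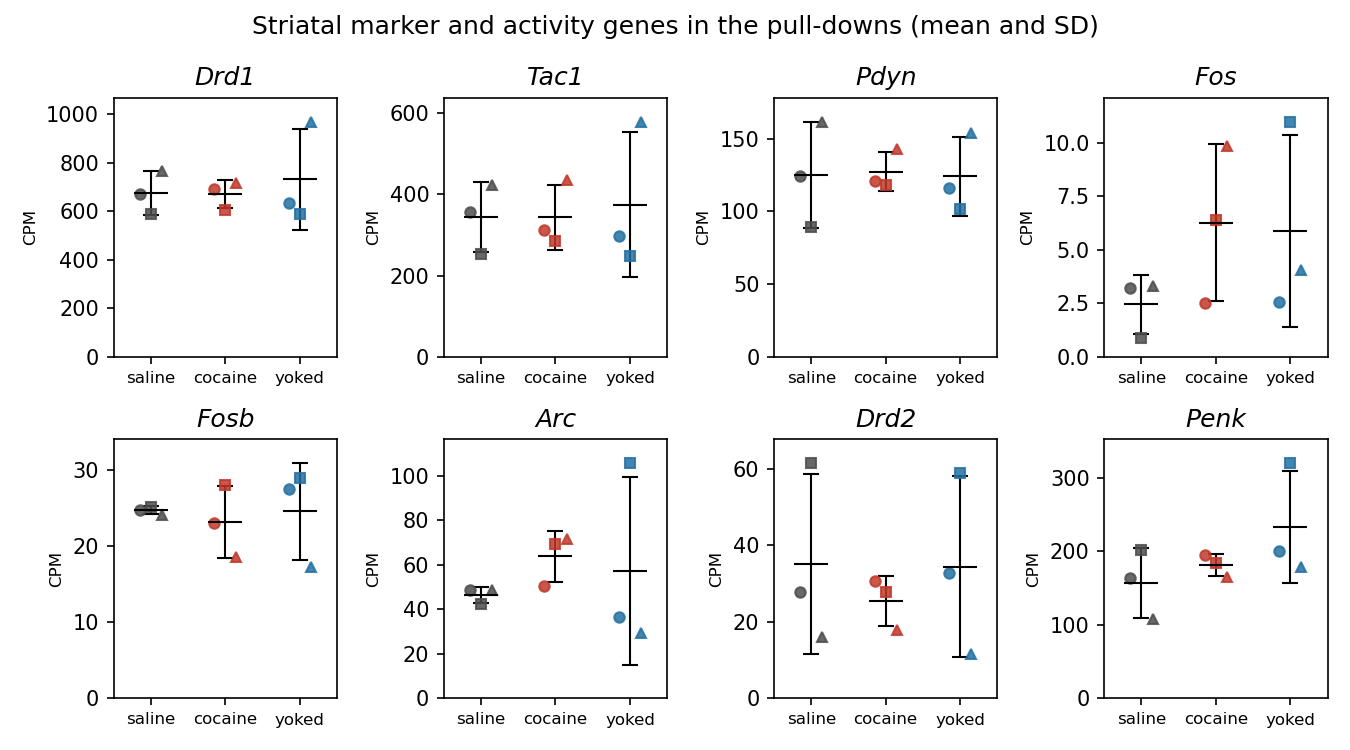
CPM of the 8 genes named in each comparison, a panel per gene, in the 9 pull-downs by group (saline grey, cocaine red, yoked blue); bars give the mean and SD of 3 libraries, and circles, squares and triangles the libraries numbered 1, 2 and 3. Drd1 averages 675, 671 and 731 CPM in saline, cocaine and yoked libraries, and Fos 2.45, 6.27 and 5.87 CPM.

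Cocaine self-administration was then compared with the yoked control. Drd1 was at 671 ± 58.1 CPM in cocaine and 731 ± 208 in yoked libraries (SD, n = 3 each), and Tac1 at 344 ± 80.2 and 375 ± 179. Log2 fold changes were 0.04 ± 0.20 (SE) for Pdyn, 0.09 ± 0.63 for Fos, -0.08 ± 0.21 for Fosb, 0.16 ± 0.42 for Arc, -0.44 ± 0.64 for Drd2 and -0.36 ± 0.23 for Penk, which was at -0.06 without yoked 2. None passed. No gene was called by edgeR (Benjamini-Hochberg, smallest adjusted p = 0.974), by DESeq2 or by limma-voom. An unadjusted edgeR p under 0.05 was reached by 379 genes, where the nominal share of 0.05 is 734 and other splits of these libraries gave 324 to 1995. Among the 10 genes of the rule, given as not passing, Nt5c, a nucleotidase (chromosome 11, 115490420 to 115492070), was at 20.7 ± 2.80 against 13.5 ± 0.52 CPM. The complex III gene Cyc1 was at 144 ± 15 against 108 ± 7.19 CPM. Log2 fold changes were 0.59 for Lypla2 and 0.45 for Lrrc73, and the clone AK034221 was 2.29-fold higher in value. Aldh1l2, a mitochondrial folate enzyme, was at 0.529 ± 0.316 against 2.09 ± 0.295 CPM, and Dnajc1, Amot, Atad5 and Entpd5 had log2 fold changes of -0.78, -0.74, -0.79 and -0.89, with Atad5 at -0.52 without yoked 3. Of genes with a mean count of at least 50, 761 of 12104 (6.29%) were separated, below the 10% of chance.

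Between cocaine and yoked libraries 4 lists were called by camera. Oxidative phosphorylation genes rose by a median log2 fold change of 0.12, with 59 of 75 higher (camera of limma, Benjamini-Hochberg adjusted p = 6.52e-08), and ribosomal protein genes by 0.19, with 72 of 80 higher (8.06e-08). For both, adjusted p = 0.887 with an estimated correlation. The oxidative phosphorylation median was 0.04 without cocaine 2, 0.06 without yoked 2, 0.21 without cocaine 1, 0.27 without yoked 3 and 0.24 without the libraries numbered 3, and the ribosomal one 0.05 without cocaine 2 and 0.33 without cocaine 1. Ion channels (-0.14, 29 of 37 lower, camera adjusted p = 0.0307 by Benjamini-Hochberg) and oligodendrocyte markers (-0.58, 12 of 12 lower, 0.0443) were lower, by camera with adjusted p = 0.887 with an estimated correlation for each (Benjamini-Hochberg). Adjusted over the list alone, 0 genes passed in any list. Fold changes ran against genomic span here too (Spearman rho -0.289 across 13288 genes). The oligodendrocyte call was lost without yoked 2, the library with the highest glial score (median 0.14, camera adjusted p = 0.839, Benjamini-Hochberg), yoked 1 (0.199) or cocaine 3 (median -0.29, 0.664), and its median was -0.95 without yoked 3 and 0.05 with the background covariate. It was also lost with camera on voom values, also chosen after the data were seen (adjusted p = 0.0522, Benjamini-Hochberg). The ion channel call was lost without cocaine 2 (median -0.02, 0.818), yoked 1 (0.0545) or yoked 3 (0.218), that of oxidative phosphorylation without yoked 2 (0.207) and that of ribosomal genes without cocaine 2 (0.102), all by camera adjusted p (Benjamini-Hochberg). Without yoked 3, 12 lists were called. Astrocyte (-0.54), microglial (-0.50), endothelial (-0.50), precursor (-0.85), D2 (-0.31) and interneuron markers (-0.44) had lower medians in cocaine without being called. The astrocyte median was 0.07 without yoked 2, 0.05 with the background covariate, which holds these markers, and -0.96 without yoked 3, and the microglial one -0.05 without yoked 2, -0.0099 with the covariate, -0.86 without cocaine 2 and -0.91 without yoked 3. The other medians were 0.0039 for immediate early genes, 0.0068 for dopamine and cAMP signalling, -0.07 for neuropeptides, -0.09 for postsynaptic genes, -0.13 for GABA signalling, -0.02 for actin and spine genes, -0.09 for chromatin regulators, -0.02 for circadian genes, 0.02 for glucocorticoid-responsive genes, -0.07 for chaperones, 0.04 for presynaptic genes, -0.32 for sex-linked genes, -0.02 for D1 markers, -0.03 for shared neuron markers, -0.06 for ependymal markers and -7.7e-04 for cortical markers. The mean had the other sign than the median for immediate early genes and cortical markers, and camera the other direction than the median for actin, circadian, D1, shared neuron and cortical lists.

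Yoked and saline libraries were compared as the 2 reference conditions. Penk (chromosome 4, 4133536 to 4138815) was at 234 ± 76.6 CPM in yoked and 158 ± 47.7 in saline libraries (SD, n = 3 each), a log2 fold change of 0.57 ± 0.23 (SE) that did not pass after adjustment (edgeR unadjusted p = 0.0295) and was 0.26 without yoked 2 and 0.36 without saline 3. Fos was at 5.87 ± 4.50 and 2.45 ± 1.39 CPM and Arc at 57.3 ± 42.3 and 46.4 ± 3.66. The log2 fold change of Fos was 1.21, and 0.37 without yoked 2, where Fos was at 11 CPM against 2.57 and 4.04 in yoked 1 and yoked 3. Log2 fold changes were 0.12 ± 0.18 for Drd1, 0.12 ± 0.30 for Tac1, -0.01 ± 0.20 for Pdyn, -0.0068 ± 0.21 for Fosb and -0.02 ± 0.64 for Drd2. No gene was called by edgeR (Benjamini-Hochberg, smallest adjusted p = 0.999), DESeq2 or limma-voom. An unadjusted edgeR p under 0.05 was reached by 270 genes, where the nominal share of 0.05 is 734 and other splits of these libraries gave 199 to 1478. The 10 genes of the rule did not pass. Acss2, an acetyl-CoA synthetase, was at 12.8 ± 1.73 against 7.99 ± 0.477 CPM, Dbt, of branched-chain amino acid breakdown, at 18.2 ± 0.943 against 12.1 ± 1.41, Idh1 at 20 ± 2.45 against 14.1 ± 1.76 and Ciart at 15.5 ± 1.21 against 9.52 ± 1.0. Mettl7a1 (2.03-fold, a log2 fold change of 1.02 that was 0.57 without yoked 3), Rsrp1 (1.62-fold), Zfp566 (1.85-fold) and the clone AK140265 (2.43-fold) had higher and Nphp4 and Cd164l2 lower values (log2 fold changes of -0.84 each). Separated genes were 755 of 11888 (6.35%), with 10% by chance.

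Between yoked and saline libraries 5 lists were called. Astrocyte markers had a median log2 fold change of 0.63 and oligodendrocyte markers of 0.54, each with 12 of 12 higher in yoked (camera of limma, Benjamini-Hochberg adjusted p = 0.0307 and 0.0443). For both, camera gave an adjusted p = 0.887 with an estimated correlation (Benjamini-Hochberg). Without yoked 2 camera gave both the other direction (medians of -0.14 and -0.20, adjusted p = 0.627 and 0.830, Benjamini-Hochberg), and they were not called without saline 3 (medians of 0.34 and 0.16, 0.813 and 0.978) or yoked 1 (0.124 and 0.208). Oligodendrocyte markers were also lost without saline 1 (camera adjusted p = 0.0743, Benjamini-Hochberg) or cocaine 2 (0.0612). The 2 medians were 1.04 and 1.14 without saline 2, 1.02 and 0.90 without yoked 3 and 0.04 and -0.12 with the background covariate. Oxidative phosphorylation genes were higher by a median of 0.16, with 62 of 75 higher (camera adjusted p = 7.91e-06 by Benjamini-Hochberg, and adjusted p = 0.887 with an estimated correlation). The call was lost without saline 3 (median 0.10, camera adjusted p = 0.1 by Benjamini-Hochberg) or yoked 3 (median 0.03, 0.619), and without the libraries numbered 3 the median was -0.04. Without saline 3 camera called 1 list and without saline 2 it called 13. Fold changes had a Spearman rho of -0.0048 with genomic span in this comparison (13288 genes), with a median of 0.03 in the tenth of genes with the shortest span and 0.0022 in the tenth with the longest. Shared medium spiny neuron markers were lower by camera (median -0.11, 11 of 14 lower, adjusted p = 0.0404 by Benjamini-Hochberg, and adjusted p = 0.887 with an estimated correlation), but not without saline 1 (median -0.07, 0.143), saline 3 (median -0.07, 0.131), yoked 2 (0.0608) or yoked 3 (0.31). That call was also lost with the background covariate, a list test likewise added later (camera adjusted p = 0.0562, Benjamini-Hochberg) and without the libraries numbered 3 (median -0.04, 0.44). The sex-linked list was higher (median 0.35, 3 of 4 higher, camera adjusted p = 0.0190 by Benjamini-Hochberg, and adjusted p = 0.887 with an estimated correlation), but not without yoked 3 (median 0.04, 0.443) or saline 1 (0.0743). Without the libraries numbered 3 its median was 0.08 (camera adjusted p = 0.351, Benjamini-Hochberg). Eif2s3y, a Y-linked gene, was the 1 member that passed when adjusted over the list alone (edgeR, Benjamini-Hochberg adjusted p = 0.0178), and stood at 25.3 CPM in yoked 3 against 7.01 to 11.8 in the other pull-downs. That adjustment does not allow for the number of lists, and over all genes 0 members were called. Outside the sex-linked list, 0 genes passed when adjusted over the list alone. The lists not called had medians of 0.11 for immediate early genes, -0.04 for dopamine and cAMP signalling, 0.10 for neuropeptides, -0.02 for postsynaptic genes, 0.03 for GABA signalling, -0.03 for ion channels, 0.02 for actin and spine genes, -0.03 for chromatin regulators, 0.07 for circadian genes, 0.10 for glucocorticoid-responsive genes, 0.09 for chaperones, 0.07 for ribosomal proteins, -0.02 for presynaptic genes, 0.0060 for D1 markers, 0.22 for D2 markers, 0.74 for precursor, 0.56 for microglial, 0.31 for endothelial, -0.16 for ependymal, 0.24 for interneuron and 0.49 for cortical markers. For D1 markers the mean and camera had the other sign than the median.

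The comparisons share libraries, so their fold changes are correlated without any effect. Log2 fold changes of cocaine against saline and yoked against saline correlated across 14680 genes at r = 0.51, and 100 simulations of unchanged groups gave a mean of 0.52. The covariance was 0.0288 against 0.0380 simulated. For cocaine against saline and cocaine against yoked, r was 0.50 against 0.50 simulated, and the covariance 0.0283 against 0.0359. In both pairs the observed covariance lay below the range of the simulations, which was 0.0352 to 0.0404 and 0.0328 to 0.0390. The simulations drew genes and libraries independently, whereas real libraries of one number had a mean correlation of deviations of 0.136 and other pairs of -0.067. The simulated values are therefore not an exact level for unchanged groups, and no conclusion is drawn from the difference. With no gene called, 0 genes were shared at the adjusted threshold.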

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

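The alternatives without the libraries numbered 3, the list tests with the background covariate or on voom values, the input comparison with each pull-down left out and the refitted simulations of shared genes were chosen after the data were seen. The count of 0 called genes stayed 0 in each comparison with median-of-ratios or upper quartile factors, no filter, the stricter filter, library sizes without the most abundant genes, a test against a 1.2-fold change and limma-voom. For cocaine against saline it was 1 by DESeq2, 1 in the fit of only the 2 groups, 1 without the libraries numbered 3 and 2 with the background covariate. AK155692 was the gene called in the first 3 of these, and it and Slc18a3 with the covariate. Slc18a3 was at 23.8 CPM in saline 2 but at 2.64 and 1.58 CPM in saline 1 and saline 3, and at 0.867 CPM or less in the cocaine libraries. Leaving out each library in turn gave 0 to 1 genes for cocaine against saline and 0 to 1 for yoked against saline, AK155692 without yoked 3 in both, and 0 for cocaine against yoked. The replicate number as a block (replicate block) called 1 gene in each comparison, Gh, and changed no other gene call. Gh was at 340 CPM in saline 1 and at 3.28 CPM or less in the other pull-downs. Between cocaine and yoked it had 108 counts in cocaine 1, 10 in yoked 1 and 1 or 0 in the others. The Gh calls therefore rest largely on the libraries numbered 1. Libraries of one number have one index sequence, but no label says that a number marks a shared animal, litter, batch or day, and 6 of 9 same-number pairs had a correlation of deviations over 0.1 (range 0.0027 to 0.23), so the libraries were taken to share only a number, although 7 of 9 correlated best with one of their own number, a hint from the data. With the block the list counts were 7, 6 and 6, as cocaine against yoked gained astrocyte and microglial markers (lower in cocaine) and yoked against saline microglial markers (higher in yoked), and in yoked against saline the camera adjusted p (Benjamini-Hochberg) was 1.12e-05 for astrocyte and 1.52e-06 for oligodendrocyte markers. These block results are at the preset correlation of 0.01. Without the block the estimated correlation in yoked against saline was 0.889 for astrocyte and 0.893 for oligodendrocyte markers, and their calls were lost with it. The block was not run with an estimated correlation. In cocaine against saline the block turned the uncalled oligodendrocyte median to 0.13.

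Of 54 values of named genes, 35 kept their direction in every alternative that gave a value. The other 19, all of the 8 always-named genes and none of them called, changed sign in 1 or more. The genes named by the rule were picked from these same data for a small p and separated groups. Leaving out a library could therefore hardly turn their sign, and the count of 35, which includes them, does not measure robustness. With the background covariate the log2 fold changes of opposite sign were Drd1 0.0056 and Tac1 0.017 for cocaine against saline, Pdyn -0.089, Fosb 0.042 and Drd2 0.25 for cocaine against yoked, Pdyn 0.15 and Arc -0.058 for yoked against saline. Without the libraries numbered 3 they were Drd1 0.040 and Fosb 0.025 for cocaine against saline, Drd1 0.082, Tac1 0.13, Fos -0.61 and Arc -0.25 for cocaine against yoked, Drd1 -0.042, Tac1 -0.17, Pdyn 0.023, Fosb 0.18 and Drd2 0.054 for yoked against saline. With the replicate block they were Tac1 0.0054 for cocaine against saline, Pdyn 6.5e-04 for yoked against saline. With no filter they were Tac1 0.0025 for cocaine against saline, Fosb 0.0022 for yoked against saline. Tac1 in cocaine against saline, at -1.1e-04 in the reported fit, was at 8.0e-04 with upper quartile factors, 1.0e-04 without the most abundant genes and 7.2e-04 by limma-voom. Leaving out each library in turn, the log2 fold changes that changed sign for cocaine against saline ranged over Drd1 -0.099 to 0.094, Tac1 -0.21 to 0.18, Pdyn -0.17 to 0.25, Fosb -0.25 to 0.041, Drd2 -0.80 to 0.21 and Penk -0.0042 to 0.43. Leaving out each library in turn, the log2 fold changes that changed sign for cocaine against yoked ranged over Drd1 -0.25 to 0.13, Tac1 -0.34 to 0.34, Pdyn -0.080 to 0.23, Fos -0.40 to 0.93, Fosb -0.28 to 0.050, Arc -0.16 to 0.96 and Drd2 -0.85 to 0.20. Leaving out each library in turn, the log2 fold changes that changed sign for yoked against saline ranged over Drd1 -0.14 to 0.24, Tac1 -0.34 to 0.34, Pdyn -0.20 to 0.22, Fosb -0.15 to 0.19, Arc -0.50 to 0.62 and Drd2 -0.65 to 0.65. The cause of these changes was not tested, and in the reported fit each of these values was smaller than its standard error.

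Camera with an estimated correlation called 0 lists in each comparison and fry 0. At the preset correlation, without the libraries numbered 3, camera called 11 for cocaine against yoked and 10 for yoked against saline, and with the background covariate 3 for yoked against saline. There, the adjusted p of camera (Benjamini-Hochberg) with the direction turned was 0.999 for astrocyte and 0.703 for oligodendrocyte markers, and 0.659 for oligodendrocyte markers in cocaine against yoked, as the covariate holds these markers. Oxidative phosphorylation in yoked against saline turned direction without the libraries numbered 3 (camera adjusted p = 0.113, Benjamini-Hochberg). Leaving out each library in turn, camera called 4 (without saline 3) to 12 (without saline 2) lists for cocaine against saline, 3 (without yoked 1) to 12 (without yoked 3) for cocaine against yoked, and 1 (without saline 3) to 13 (without saline 2) for yoked against saline. The camera adjusted p (Benjamini-Hochberg) ranged from 3.13e-04 to 0.818 for ion channels and from 9.25e-06 to 0.839 for oligodendrocyte markers in cocaine against yoked. In yoked against saline it ranged from 1.44e-10 to 0.813 for astrocyte and from 3.98e-07 to 0.978 for oligodendrocyte markers. The cause was not tested.

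A pseudocount of 2 CPM moved the log2 ratio to the input to -1.42 for microglial, -0.58 for endothelial, -0.67 for ependymal and -0.74 for blood markers. Other scalings moved no list by more than its spread, the SD over the 9 pull-downs. Leaving out single pull-downs did not either, but 1 of 9 libraries can hardly move a mean that far. The single input, on which every ratio rests, could not be left out. At an unadjusted p under 0.01, 4 genes were shared in the same direction by cocaine against saline and yoked against saline, and 3 by cocaine against saline and cocaine against yoked (47 genes passed in the first comparison, 23 in yoked against saline and 30 in cocaine against yoked), where 30 simulations of unchanged groups sharing these libraries gave a mean of 19.5 (10 to 29) and 18.9 (11 to 28). These simulations drew genes and libraries independently. Real libraries of one number were correlated (mean r of deviations 0.136, against -0.067 for other pairs), so no conclusion is drawn from the lower real counts. Depth limits genes near the floor most in saline 2, where 3 counts are 0.239 CPM.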

Other observations

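The tests of replicate number, treatment group (over all libraries and within replicate numbers) and cortical markers below, and the values of single genes and libraries in the next paragraph, were chosen only after the values were seen, whereas those of gene length, background and splits of the libraries were set before their results were.

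Some transcripts stood out in single libraries. Growth hormone, Gh, was at 2360 CPM in the input and 340 CPM in saline 1, and at 3.28 CPM or less in the other 8 pull-downs. Prolactin, Prl, was at 174 CPM in the input and 23.6 in saline 1, and Pomc at 93.9 and 17.8. Transthyretin, Ttr, a choroid plexus product, was at 147 CPM in saline 3 against 7.77 in the input. The vesicular acetylcholine transporter gene Slc18a3 was at 23.8 CPM in saline 2 against 7.87 in the input, and Chat, of the same cholinergic cells, at 12.5 against 6.86. The relation to genomic span differed between libraries within each group. Across genes, the deviation of a library from the mean of all 9 had a Spearman rho with span of -0.342 in cocaine 2 and -0.219 in cocaine 3 but 0.109 in cocaine 1. This rho was 0.0142, 0.0464 and 0.195 in saline 1, saline 2 and saline 3, and -0.048, 0.185 and 0.0522 in yoked 1, yoked 2 and yoked 3.

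The higher oxidative phosphorylation list after cocaine was set against gene length and background, as its members span little genome (median 7.20 kb against 25.1 kb for the genes tested, 72 of 75 with a span). The median log2 fold change of 0.28 stood at percentile 100 of 10000 lists matched on expression and genomic span, whose median was 0.08 (95% between 0.04 and 0.12). Genomic span in 10 bins thus did not give the whole shift, but gene length stays open. Transcript length was not tested. The random lists hold unrelated genes, whereas the estimated correlation within this list was 0.477. Pull-down background from other cells stays open, since the background covariate, with which the median was 0.28 (95% bootstrap interval 0.26 to 0.30), holds no neuronal markers and differed between the groups (1.66 in cocaine, 1.64 in saline) by less than its SD within them (0.68), too little to move this contrast. Over the 9 libraries the list score had a Pearson r of -0.329 with the glial score (exact permutation p = 0.382, adjusted 0.382 over 2 relations by Benjamini-Hochberg) and a Spearman rho of -0.217 (exact permutation p = 0.581, adjusted 0.581), and r was -0.697 without saline 3 and yoked 2. The tests of gene length and of the covariate treat genes as independent, the call ended with an estimated correlation (adjusted p of 0.887 by camera with Benjamini-Hochberg adjustment), and the treatment cannot be told apart from the sequencing lane.

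The glial marker level differed by replicate number. Of the 280 groupings of the 9 libraries into 3 sets of 3, a share of 0.0107 had as large a variance between sets as the replicate numbers, and 0.761 as large as the treatment groups. This is consistent with replicate number as a preparation batch, a hypothesis found and tested on the same libraries. The treatment group stays open, since with the replicate numbers kept a share of 0.333 of the 36 arrangements of the groups had as large a variance between groups, and yoked lay above saline in 3 of 3 numbers. Index sequence goes with the number in the labels, so its effect was not separated from that of preparation.

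The median of the cortical glutamatergic markers was above the input in 7 of the 9 pull-downs, and low in saline 1 and yoked 2. Their most abundant gene, Slc17a7, was at 33.2 ± 17.3 CPM (SD, n = 9). If cortical RNA were retained in proportion to glial RNA, the cortical score would rise with the glial score. The relation was Pearson r = -0.522 (exact permutation p = 0.163, adjusted 0.326 over 2 relations by Benjamini-Hochberg) and Spearman rho = -0.40 (exact permutation p = 0.291, adjusted 0.581) over 9 libraries, two-sided. Without saline 3 and yoked 2, the libraries farthest from the median glial score, r was -0.21. The test does not decide on retention, since the amount of cortical RNA in each dissection was not measured and need not follow that of glia. Glial lists lay at 0.128 to 0.208 of the single input and the cortical list at 1.57, but 2 of the 10 cortical genes were below it in all 9 pull-downs. Cortical cells carrying the tag were not tested. Lanes hold 3 libraries of 1 group each, and a relation pooled within lanes was not computed. 

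Other splits of the 6 libraries of each comparison were compared with the real one. For called genes, the real split gave 0 in each comparison by edgeR (417, 379 and 270 genes at an unadjusted p under 0.05), so 10 of 10 splits gave as many, and the highest other count was 0, 0 and 1 for cocaine against saline, cocaine against yoked and yoked against saline. At an unadjusted p under 0.05 the other splits gave 149 to 739, 324 to 1995 and 199 to 1478 genes, in the same order. For called lists, the real counts were 7, 4 and 5. In 6, 10 and 8 of the 10 splits as many lists were called, the real one included, and the highest other count was 12, 16 and 16. With 10 splits no share can fall under 0.05. The counts are by camera at its preset correlation, with which other splits called up to 16 lists, whereas with an estimated correlation the real splits called 0. The 16 lists came from parting cocaine 1, cocaine 2 and yoked 2 from cocaine 3, yoked 1 and yoked 3, and saline 1, saline 2 and yoked 2 from saline 3, yoked 1 and yoked 3.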
